A study of Mus musculus with 6 samples.

How the data were processed

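Pancreas sections from 6 mice with cerulein pancreatitis were studied, 3 labelled WT (floxed Hbp1, no Cre) and 3 labelled CKO (p48Cre with floxed Hbp1). Each genotype had 2 mice at 24 h and 1 mouse at 48 h after the last of 7 cerulein injections. Samples taken at 7 days, which the treatment protocol mentions, were not analysed here. Per the labels, tissue was fixed in paraformaldehyde, embedded in paraffin and cut at 4 µm for the Visium spatial assay, which reads pairs of gene-specific probes. The deposited matrices hold raw UMI counts per gene and spot (unit: counts), per the file headers written by Space Ranger 2.1.1, and the submitters' processing notes name the genome build mm10. The deposited positions files hold the tissue flag and the array grid position of each spot (unit: other). Every spot in the matrices was marked as tissue, and the files list 19465 genes. Probe sequences and the exons of Hbp1 that were deleted are not given in the sources used here.

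Counts were summed over all tissue spots of each mouse, since spots of a section are not independent replicates. Differential expression was tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, using TMM scaling, the filterByExpr filter on the 4 groups and the quasi-likelihood F test. The genotype test used hours after cerulein as a covariate, and the time test came from the same fit. The genotype contrast at 24 h and the genotype by time interaction came from a model with a mean per group. In that model the single mice at 48 h were assumed to vary like the 24 h mice. The 48 h genotype comparison, with 1 mouse each, had no test. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. CPM values are counts relative to the TMM-scaled library size, except for Hbp1, where the plain library size was used unless stated. TMM factors ran from 0.684 to 1.29. Standard errors (SE) of log2 changes were derived from the p-value. In the main fit to whole sections, every gene took its spread from the trend over all genes. The p-values and SE of that fit therefore do not reflect how far a gene's own values differed between mice. The smallest and largest library totals were 2969981 and 14868447 UMIs.

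Spots with at least 250 UMIs were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on Python 3.11.15. Counts were scaled to 10000 per spot and log-transformed, 2000 variable genes were centred per mouse, and 30 principal components and 15 neighbours were used at Leiden resolution 0.5. The clusters are regions of tissue, named by their leading genes, not cell types. A region was called acinar when at least 3 of its top 10 genes by fold were acinar enzymes. The genotype test was repeated on counts summed over the acinar region and over any other region with at least 20 spots in at least 2 mice of each genotype, which left the region led by Arg1.

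Gene lists were fixed before the data were examined, as were the comparisons and most alternatives. Of 558 list entries, 517 were measured, 3 of them matched through a synonym. Lists named below cover islet, T and NK cell, B cell, plasma cell, neutrophil, macrophage, fibroblast and duct genes, acinar enzymes, acinar identity regulators, Reg and injury genes, endoplasmic reticulum stress, interferon response, cytokines and chemokines, cell cycle and reported HBP1 targets. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Shares of UMIs or spots and within-section Spearman correlations were compared between genotypes by exact two-sided permutation of 3 against 3 mice, whose smallest possible p is 0.1. Confidence intervals of shares are exact Clopper-Pearson intervals at 95%. They and the limit of 3 counts that a count of 0 allows cover counting error only.

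Named genes followed a fixed rule. Hbp1 came first, then the genes past the threshold with at least 20 CPM in some group and no overlap between the compared groups, by size of change, 12 per direction (6 for the 24 h, interaction and region tests). Free places went to the smallest unadjusted p and are given as not past the threshold. Up to 4 members with the smallest p were named per list. Genes outside the rule are marked where they appear. The pipeline was tested on simulated counts with 200 changed genes. All genes of a test were simulated with the same dispersion, and only genes above a minimum level were changed. No section was made to differ in composition, so the percentages below are not error rates for the real data. For the genotype test on whole sections (18043 genes), 62% of 4-fold and 4% of 2-fold changes were recovered, and 2.94% of the calls were false. The time test recovered 50% and 0%, the acinar test (12283 genes) 84% and 11%, and the test in the Arg1-led region (12723 genes) 72% and 3%. The alternatives fixed together with the gene lists were DESeq2 1.42.0, no TMM, no filter, a minimum of 1000 UMIs per spot, thinning to the smallest library, removal of acinar enzyme and Reg genes, no covariate, a block for the number at the end of the file names, limma-voom with quality weights, a mean over spots, other clusterings, a random 100 spots per mouse, and leaving out each mouse in turn. Other dispersion settings, the 24 h mice alone, removal of spots of single regions and every alternative in the Arg1-led region were added after the data were seen.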

Results

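Spatial transcript counts were obtained from pancreas sections of 6 mice with acute pancreatitis caused by cerulein, a peptide that overstimulates enzyme secretion, given as 7 hourly injections of 50 µg/kg. The study asked how loss of the transcriptional repressor HBP1 in the pancreas affects this injury. Per the labels, areas with pancreatitis were chosen for mounting, so tissue composition depends on that choice. The sections labelled WT came from 2 mice at 24 h and 1 at 48 h, and those labelled CKO likewise. The WT-labelled sections covered 353 and 324 spots at 24 h and 714 at 48 h, with 3958425, 4201051 and 2969981 UMIs. The CKO-labelled sections covered 1323 and 1646 spots at 24 h and 736 at 48 h, with 10361487, 14868447 and 4709496 UMIs. The largest total was 5.01 times the smallest, and the median depth per spot ran from 3105.5 to 12735.5 UMIs. A single gene, the chymotrypsinogen Ctrb1, took 21.3 to 33.1% of the UMIs of each section. The Y-linked genes Eif2s3y and Ddx3y had 113 and 49 UMIs in the WT-labelled 24 h replicate 1 and 0 UMIs in the 5 other sections, where up to 3 UMIs are allowed by a count of 0. The labels do not state the sex of the mice.

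Hbp1, the gene targeted in the CKO-labelled mice, was not lower in them. Its level was 68.7, 72.8 and 60.6 CPM in the WT-labelled and 86.4, 112.2 and 101.7 CPM in the CKO-labelled sections. The means were 67.4 ± 6.22 and 100.1 ± 12.98 CPM (SD, n = 3 each), a ratio of 1.49 (exact permutation p = 0.1, the smallest that 3 against 3 allows). In the acinar regions, the means were 46.9 ± 23.5 and 90.8 ± 17.8 CPM, a ratio of 1.94 (exact permutation p = 0.1). The 48 h sections held few Hbp1 UMIs there, 30 in the WT-labelled and 26 in the CKO-labelled one. In the other spots the ratio was 1.25 (exact permutation p = 0.2). With TMM scaling the groups overlapped, the ratio fell to 1.14, and edgeR gave a log2 change of 0.19 (SE 0.33, adjusted p = 1.0). The log2 change was -0.03 without the WT-labelled 24 h replicate 2 and -0.05 without the CKO-labelled 24 h replicate 2. Which exons were deleted and where the Hbp1 probes bind is not given, so these counts may be blind to the deletion. Ptf1a, the acinar transcription factor also called p48, averaged 50.5 ± 13.3 CPM in the WT-labelled and 24.7 ± 7.71 CPM in the CKO-labelled mice (SD, n = 3 each). All 3 CKO-labelled values lay below all 3 WT-labelled values, a log2 change of -1.04 (SE 0.33, adjusted p = 0.253, not past the threshold). Since Hbp1 itself does not separate the groups in the direction of the labels, every genotype comparison below is between labels.

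**Figure D1:**
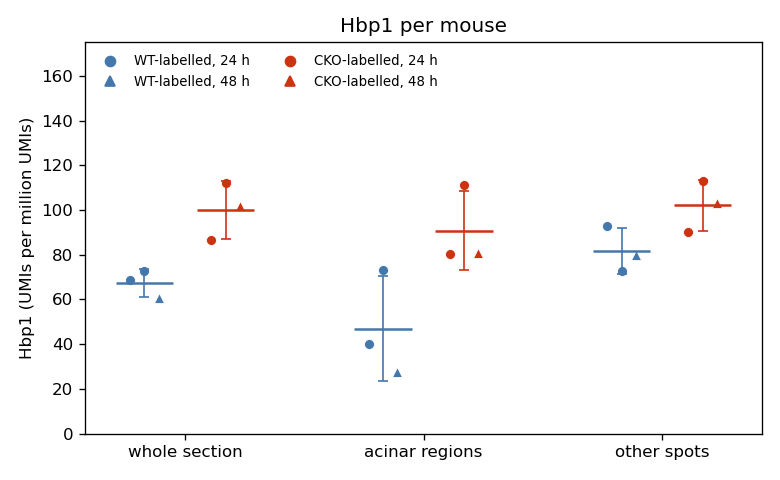
Hbp1 in CPM of library size for each mouse over the whole section, the acinar regions and the other spots. Points are mice, lines are group means and error bars are SD (n = 3 per genotype), with means of 100.1, 90.8 and 102.1 in the CKO-labelled and 67.4, 46.9 and 81.7 in the WT-labelled mice.

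Between genotype labels, Ckb, Marco and Arg1 were higher and Klk1b11 and Klk1b4 lower in the CKO-labelled sections. Ckb, the brain-type creatine kinase, rose from 14.2 ± 6.01 to 38.5 ± 8.99 CPM (SD, n = 3 each), a log2 change of 1.51 (SE 0.35, adjusted p = 0.00735). Marco, a scavenger receptor of macrophages, rose by 3.55 on the log2 scale (adjusted p = 4.1e-10), with 7.09, 6.96 and 98.4 CPM against 2.22, 1.35 and 0.846. That p-value does not reflect the spread between these mice. S100a8, a neutrophil calcium-binding protein, rose by 2.32, the integrin regulator Acap1 by 2.13, the T cell receptor chain Trbc2 by 1.99 and the granule proteoglycan Srgn by 1.35. Of these, Marco, S100a8, Acap1 and Trbc2 had their highest value in the CKO-labelled 48 h section, and Marco was among the leading genes of the lymphoid region of that section. Arg1, the arginine-degrading enzyme of macrophages in injured tissue, rose by 1.64 (SE 0.36, adjusted p = 0.00353), from 26.2 and 67.0 to 162 and 198 CPM at 24 h and from 8.04 to 14.0 at 48 h. It was chosen after its values were seen. Klk1b11 and Klk1b4, tissue kallikreins with closely related sequences whose probes may be shared, fell by 2.42 (adjusted p = 1.9e-08) and 1.44 (adjusted p = 0.00686). The lipid droplet enzyme Hsd17b13 fell by 1.43, the glycolipid synthase Gbgt1 by 1.33 and the deacetylase homologue Ydjc by 1.26. Gbgt1 was at 42.6 ± 9.84 and 16.9 ± 4.04 CPM, and Ydjc at 42.8 ± 7.92 and 17.8 ± 1.25 CPM (SD, n = 3 each).

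In that test 55 of 18043 genes passed the threshold, 41 higher and 14 lower in the CKO-labelled mice. Of the 41 higher genes, 34 had their highest value in the CKO-labelled 48 h mouse, and of the 14 lower genes 11 had theirs in the WT-labelled 24 h replicate 1, the section with Y-linked transcripts. For the lower genes, a difference by sex may therefore add to a difference by label, and its part was not tested. Whichever mouse was left out, Klk1b11, Klk1b4, Hsd17b13, Gbgt1 and Ydjc stayed at a log2 change of -0.75 or below. These genes had been named for groups without overlap, so that does not exclude a part of sex. The groups did not overlap for 14 of the 55, and for 4.98% of all genes, where chance gives 10%. Without either 48 h mouse, the time covariate fits the other one exactly, and the genotype test uses the 24 h mice alone. The count depended on which libraries were used. It was 32 without the WT-labelled 24 h replicate 1, 110 without the WT-labelled 24 h replicate 2, 14 without the WT-labelled 48 h mouse, 3 (Marco, Pla2g2d and Gm4737) without the CKO-labelled 24 h replicate 2 and 16 without the CKO-labelled 48 h mouse. Without the WT-labelled 24 h replicate 1 none of the 14 lower genes passed (edgeR, with 0 lower calls of 32), and Klk1b11 was at -1.17. DESeq2 called 1 gene, the Y-linked Eif2s3y, and limma-voom with quality weights called 645, 328 higher and 317 lower. Without TMM 32 genes passed, 90.6% of them higher against 74.5% with it, and the median log2 change of all genes moved from 0.04 to 0.37. Below the threshold, the smallest p values belonged to Dusp2, Nat8, S100a9, Runx3 and Resp18 among higher genes (log2 1.38 to 2.02) and to Stc2, Anxa10, Defb1, Rab6b, Reep6, Pnliprp2 and Sdc1 among lower genes (log2 -1.44 to -1.06).

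**Figure D2:**
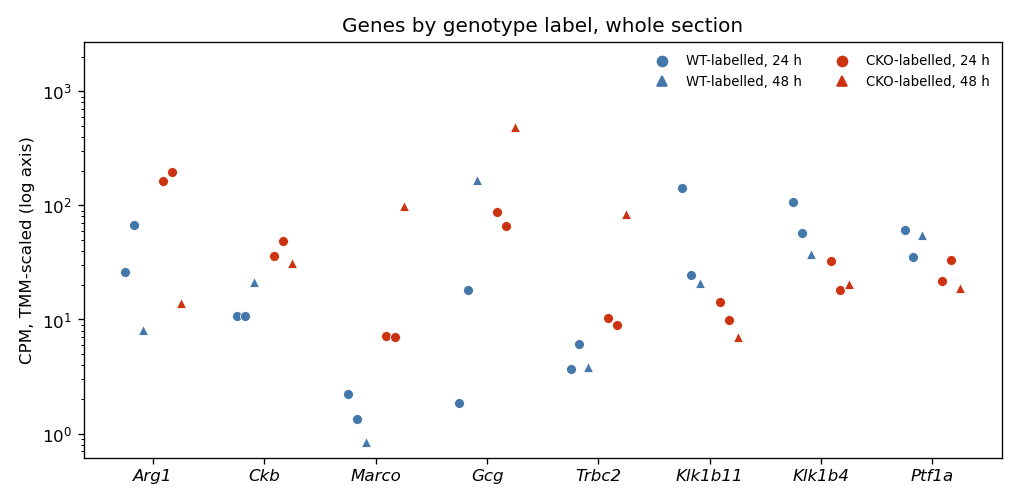
TMM-scaled CPM (log axis) of 8 genes in each of the 6 whole sections, by genotype label and time. Arg1 was higher in the CKO-labelled mice at each time, Ckb, Marco and Trbc2 were higher and Klk1b11, Klk1b4 and Ptf1a lower in all 3 CKO-labelled mice, and Gcg was highest in the CKO-labelled 48 h mouse.

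Among fixed gene lists, islet genes and T and NK cell genes had the highest medians in the CKO-labelled sections relative to the WT-labelled ones, and acinar enzymes and endoplasmic reticulum stress genes the lowest. Of 16 islet genes, 6 rose (12 when adjusted over the list alone) with a list median of 1.41. The smallest p values were those of Gcg (glucagon, log2 2.38), Chga (chromogranin A, 2.29), Ins1 (insulin, 2.21) and Iapp (amylin, 2.03). Without the WT-labelled 24 h replicate 1, whose section held no islet-led spot, none of these 6 passed in edgeR (log2 1.43 to 1.90). Of 17 T and NK cell genes, 4 rose (11 when adjusted over the list alone, median 1.26), namely Trac, Cd3d, Trbc2 and Cd3e. Without the CKO-labelled 48 h mouse none of these passed in edgeR, nor did Cd79b or Igha (median 0.65 over the 6), and these genes were highest in that mouse, where the T and NK cell list took 0.0741% of UMIs against at most 0.00736% elsewhere. The B cell list had 1 called gene of 13, Cd79b (6 alone, median 1.09), the plasma cell list 1 of 9, Igha (4 higher and 1 lower alone, median 1.03), the neutrophil list 1 of 13, S100a8 (4 alone, median 0.60) and the macrophage list 1 of 19, Marco (1 higher and 1 lower alone, median 0.16, adjusted p = 0.116). Of 19 endoplasmic reticulum stress genes, 1 fell, the pseudokinase Trib3 (log2 -1.50), and 18 were negative, with a median of -0.49. Ern1 (the stress sensor IRE1), Asns and Sesn2 were at -0.84, -0.92 and -0.77 and did not pass. None of 19 interferon response genes passed (7 alone, median 0.75), with Irf7 at 1.28, Usp18 at 1.06 and Gbp3 at 1.05. None of 26 acinar enzymes passed (1 higher and 1 lower alone, median -0.504), with Ctrc at 1.94, Pnliprp2 at -1.29, Spink1 at -1.12 and Amy1 at -0.59. The acinar identity regulators had none of 14 (1 lower alone, Ptf1a, median -0.17), Reg and injury genes none of 18 (median -0.35) and duct genes none of 17 (1 lower alone, median -0.29).

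Reported HBP1 targets and cell cycle genes did not pass as lists between genotype labels in whole sections. Of 12 reported targets none passed (median -0.05, adjusted p = 0.321), with the cell cycle inhibitor Cdkn1a at -0.81, the oxidase subunit Ncf1 at 0.61, Cdkn1b at -0.45 and Dnmt1 at 0.44. Of 27 cell cycle genes none passed (median 0.17, adjusted p = 0.0956), with Birc5 at 0.59, Mki67 at 0.48, Stmn1 at -0.48 and Ccna2 at 0.41. In the Arg1-led region 19 of 24 cell cycle genes were positive and camera called that list (median 0.22, adjusted p = 0.0411), but not with its own correlation (adjusted p = 0.451 with an estimated correlation). That call was not particular to the cell cycle. Camera called the islet, cytokine, fibroblast and macrophage lists there with smaller adjusted p, and none of these with an estimated correlation. In whole sections camera called 19 of 33 lists with its preset correlation, and none kept its call in camera (lowest adjusted p = 0.331 with an estimated correlation). Fry called none in a single direction (lowest adjusted p = 0.704).

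At 24 h alone, with 2 mice per label, hormone genes of the islets were higher and Klk1b11 lower in the CKO-labelled mice. Chga rose by 2.94, Ins2 by 2.86, Ins1 by 2.85, Gcg by 2.85, Iapp by 2.56 and the prohormone convertase inhibitor Pcsk1n by 2.15, and Klk1b11 fell by 2.77 (adjusted p = 6.4e-06). These sizes depended on single WT-labelled libraries. Without the WT-labelled 24 h replicate 1 Klk1b11 was at -0.94, Chga at 2.26, Ins2 at 2.00 and Iapp at 1.81, none of them past the threshold in edgeR, and without the WT-labelled 24 h replicate 2 they were at -3.56, 5.93, 7.05 and 5.69. Arg1 rose by 1.93 (adjusted p = 0.0224). Klk1b1, Cd209f, Klk1b4, the Y-linked Kdm5d and Klk1b8 had the next smallest p values among lower genes and did not pass. The test called 14 genes, 11 higher and 3 lower (Klk1b11 and the Y-linked Eif2s3y and Ddx3y). Of the 14, 11 separated the groups. Of all genes 15.4% did, a smaller share than chance gives for 2 against 2 mice. DESeq2 called 0 genes at 24 h, with 71 at an unadjusted p under 0.05, against 14 and 146 in edgeR. The count was 2 (Ctrc and Gm4737) without the WT-labelled 24 h replicate 1, 100 (51 higher and 49 lower) without the CKO-labelled 24 h replicate 1 and 36 without the CKO-labelled 24 h replicate 2, and 7 without TMM (median of all genes 0.18). At 48 h each label had 1 mouse and no test was made. There the log2 ratio of CKO-labelled to WT-labelled TMM-scaled CPM, with 1 CPM added to each, was 0.73 for Arg1, 1.54 for Gcg and -1.50 for Ptf1a. For Hbp1 it was 0.05, while the plain library size gave 101.7 against 60.6 CPM.

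The change of the genotype difference between times was tested with 1 mouse per label at 48 h, so its calls rest on those single sections. Interaction values above 0 belonged to Ighg2b and Ighg3 (immunoglobulin chains), Glycam1 (a mucin of lymph node venules), Dusp2, the lectin Cd209b and the chemokine Ccl5. Glycam1 was at 1482 CPM in the CKO-labelled 48 h section and at or below 2.59 CPM elsewhere. Values below 0 belonged to the stomach peptide Gkn3 and the globins Hbb-bt and Hba-a2. Hbb-bs, Mest and Gcnt1 came next and did not pass. The test called 36 genes, 33 above and 3 below 0. It called 8 and 11 without the WT-labelled 24 h replicates 1 and 2, 209 and 115 without the CKO-labelled 24 h replicates 1 and 2, 11 with DESeq2, and 12 without TMM, where the median of all genes moved to 0.55. Without the spots of the lymphoid and islet regions 1 gene passed, Glycam1.

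From 24 h to 48 h, Cilp, Thbs4 and Igha were among the genes that rose, and Ccl7, Arg1, Ccl9 and Ccl6 among those that fell. Time cannot be told apart here from a possible difference in processing. Both 48 h sections had the number 3 at the end of their file names and spot diameters of 222.73 and 222.78 pixels. The 24 h sections had the numbers 1 or 2 and diameters of 238.49 to 238.78 pixels. The labels do not explain these numbers. Cilp, a matrix protein of cartilage and scar, rose by 3.57 (SE 0.34, adjusted p = 5.9e-22), from 9.95 ± 4.12 CPM (SD, n = 4) to 118 ± 15.3 CPM (SD, n = 2), and the matrix protein Thbs4 rose by 3.97. The antimicrobial peptide Camp rose by 4.97, the immunoglobulin chains Igkc, Ighd, Ighm, Igha and Ighg2c by 4.84, 3.94, 3.79, 3.77 and 3.66, the T cell receptor component Cd3g by 3.28, Gkn3 by 3.24, Chga by 3.58 and Gcg by 3.33. The monocyte chemokine Ccl7 fell by 4.39 (adjusted p = 8.9e-17), Arg1 fell by 3.19, the calcium-binding protein S100g fell by 2.69, Ccl9 fell by 2.54, the granzyme inhibitor Serpinb9 fell by 2.47 and Ccl6 fell by 2.24. Tmc5, the interferon-induced Rsad2, the stress hormone Fgf21, the sterol synthesis enzymes Msmo1 and Cyp51 and the mucin Muc1 fell by between 2.21 and 1.90. Over single mice left out, Muc1 ranged from -2.58 to -0.89, Rsad2 from -2.71 to -1.23 and Fgf21 from -2.86 to -1.25. The test called 304 genes, 238 higher and 66 lower at 48 h, and 195 of the 304 separated the times (15.3% of all genes did). It called 107 with DESeq2 and 133 without TMM. With either 48 h mouse left out, the test set the other against the 24 h mice of its own label only. It called 375 (193 higher and 182 lower) without the CKO-labelled 24 h replicate 1, 178 without the WT-labelled 24 h replicate 1, 179 without the WT-labelled 48 h mouse, 112 without the CKO-labelled 24 h replicate 2 and 38 without the CKO-labelled 48 h mouse.

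Among lists, 7 of 9 plasma cell genes rose from 24 h to 48 h (median 3.66), as did 11 of 16 islet genes (median 1.65), 10 of 17 T and NK cell genes (median 2.06) and 8 of 13 B cell genes (12 when adjusted over the list alone, median 1.89). Of 17 fibroblast genes, 5 rose (11 higher and 1 lower when adjusted over the list alone, median 1.09), namely Dcn by 1.45, Col6a1 by 1.42, Lum by 1.33, Col6a2 by 1.35 and Col5a1 by 1.25. Decorin (Dcn) and lumican (Lum) are matrix proteoglycans. No duct gene passed (8 lower and 1 higher when adjusted over the list alone, median -0.63), with Krt19 at -1.27, Cldn4 at -1.26, Ambp at 1.16 and Prom1 at -1.10. Of 26 cytokine and chemokine genes Ccl7, Ccl9, Ccl2 and Ccl6 fell and Ccl5 rose (median -0.31, adjusted p = 0.617 with an estimated correlation). Of 26 acinar enzymes Amy2a5 and Cela3a rose and Ctrc, which differed widely among mice of the same label, fell (median -0.004). The time lists called by camera numbered 10 of 33, and none kept its call (lowest adjusted p = 0.151 with an estimated correlation). Igha passed in every alternative (log2 2.02 to 4.66), while without the CKO-labelled 48 h mouse, whose section held the lymphoid region, Cd3g was at 0.48, Ighm at 0.83, Igkc at 0.89, Ighd at 1.04, Ighg2c at 2.34 and Camp at 2.70, and none of them passed in edgeR. Gkn3 was at 0.95 without the WT-labelled 48 h mouse. With either 48 h mouse left out, the fit sets the other against the 24 h mice of its own label only.

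Clustering divided the spots into 7 regions. Region 1 (1958 spots) was led by Arg1, Ccl6, Ccl9, Ccl7 and Fn1, region 2 by globins, Mgp and Tagln, region 3 by islet hormones, region 4 by Msx3 and Fgf5, region 5 by acinar genes such as Pnlip, Prss3 and Bhlha15, region 6 by Glycam1, Igkc and Ighm, and region 7 by Cilp and Apoe. The islet-led region covered 1.85 ± 1.63% of spots in the WT-labelled and 5.03 ± 2.21% in the CKO-labelled sections (SD, n = 3 each, exact permutation p = 0.1). The nearest values were 3.08% in the WT-labelled 48 h section and 3.16% in the CKO-labelled 24 h replicate 2. Their 95% exact intervals overlap (1.94 to 4.63% and 2.37 to 4.12%). In the WT-labelled 24 h replicate 1 the share of the islet-led region was 0, which exact binomial limits allow to be up to 1.04%. Region 6 lay almost wholly in the CKO-labelled 48 h section (97 of 98 spots), where it covered 13.2% of spots (95% exact interval 10.8 to 15.8%). Region 4 lay mainly in the CKO-labelled 24 h replicate 1 (156 of 173 spots), so it may be a property of its library. Region 7 (510 spots) occurred in the CKO-labelled 48 h section alone. Without centring per mouse, a region led by Cilp, Mgp and Apoe covered 60.5% of the WT-labelled and 79.2% of the CKO-labelled 48 h section. It covered at most 1.13% of any 24 h section, so the occurrence of region 7 in 1 section depended on the centring. Regions 1 and 5 covered 49.3 ± 11.2% and 42.4 ± 5.81% in the WT-labelled and 29.8 ± 24.6% and 30.6 ± 20.4% in the CKO-labelled sections (exact permutation p = 0.3 and 0.4). Values were centred per mouse before clustering, so shares are relative within each section.

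**Figure D3:**
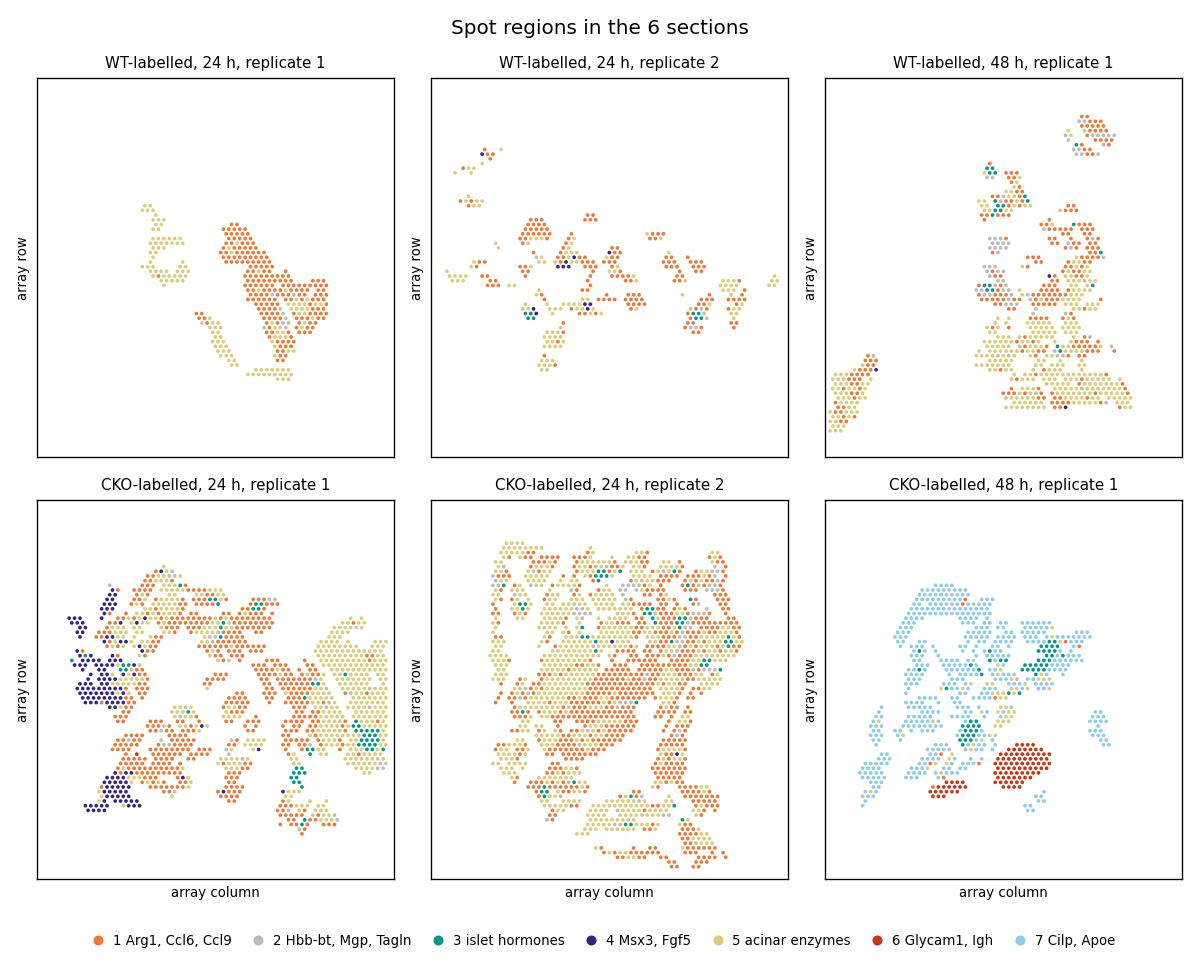
Tissue spots of the 6 sections at their array positions, coloured by region. The 97 spots of region 6 and the 510 spots of region 7 lie in the CKO-labelled 48 h section, and the WT-labelled 24 h replicate 1 has no islet-led spot.

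Within the acinar regions, the spots led by acinar genes, Ckb rose and Klk1b11 and Klk1b4 fell in the CKO-labelled mice. Ckb went from 8.46 ± 2.95 to 27.4 ± 11.4 CPM (SD, n = 3 each), a log2 change of 1.90 (SE 0.40, adjusted p = 0.00204). The contractile genes Tagln and Tpm2 rose by 2.20 and 1.54, and the hormones Ins1 and Gcg by 4.27 and 3.30. Of 13 alternatives, Tagln kept its call in 8 and Tpm2 in 3. Over single mice left out they ranged from 1.25 to 2.97 and from 1.17 to 2.26. Ins1 and Gcg are islet hormones, and the source of their RNA in these spots was not tested. Klk1b11 fell by 2.47 (adjusted p = 2.7e-08) and Klk1b4 fell by 1.40 (adjusted p = 0.0272). Gbgt1, Ydjc, Pnliprp2 and the neuropeptide Gal came next at -1.32, -1.31, -1.52 and -1.22 and did not pass. Ptf1a was at -0.89 and Hbp1 at 0.66 (adjusted p = 0.88 and 1.0). The acinar enzyme list had none of 26 past the threshold and a median of -0.64. The test called 18 of 12283 genes, 14 higher and 4 lower (with the Y-linked Eif2s3y and Ddx3y), and 8 of the 18 separated the groups (6.59% of all genes did). It called 10 without the WT-labelled 24 h replicate 1, where no lower gene passed and Klk1b11 was at -1.23, 52 (23 higher and 29 lower) without the WT-labelled 24 h replicate 2, 33 without the CKO-labelled 24 h replicate 1, 5 (Gcg, Klk1b11, Ins2, Eif2s3y and Ddx3y) without centring per mouse and 8 without TMM, where the median of all genes moved to 0.26. The CKO-labelled 48 h section gave 56 acinar spots and the other sections 124 to 764. Acinar enzymes took 44.8% of the UMIs of that section, and at resolution 1 its region 7 split off 360 spots led by Derl3, Pim3, Fkbp11 and Amy2a5.

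In the region led by Arg1, Ckb rose by 2.14 (SE 0.45, adjusted p = 0.00329) between labels, from 15.8 ± 7.01 CPM (SD, n = 3) to 52.0 ± 3.37 CPM (SD, n = 2). Klk1b11 fell by 3.10 and Klk1b4 fell by 1.83. Only the WT-labelled section entered at 48 h, and the time covariate fits it exactly. The CPM means include that section, but the log2 changes rest on the 24 h mice, 2 per label. Arg1 also passed, with a log2 change of 2.41, but it leads the region, so its change there is not taken as a result. The next genes, not past the threshold, were Srgn, the macrophage gene Retnla, the protease inhibitor Slpi and Wfdc17 above 0 and Gbgt1, Klk1b1, Hsd17b13 and Rab6b below 0. This test used 5 mice, as the CKO-labelled 48 h section had 10 such spots, and called 9 of 12723 genes, 6 higher and 3 lower (with Eif2s3y). No lower gene passed without the WT-labelled 24 h replicate 1 or without the CKO-labelled 24 h replicate 2, with Klk1b11 at -1.20 in the former. Its count was 2 without the WT-labelled 24 h replicate 1, 30 (13 higher and 17 lower) without the WT-labelled 24 h replicate 2 and 27 without the CKO-labelled 24 h replicate 1.

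The share of UMIs taken by marker lists did not separate the genotype labels for any of 33 lists (exact permutation, smallest p = 0.2). T and NK cell genes took 0.00336 ± 0.00133% and 0.0285 ± 0.0395% of UMIs, islet genes 0.0568 ± 0.0707% and 0.225 ± 0.221%, and acinar enzymes 51.3 ± 7.33% and 46.1 ± 3.07% in the WT-labelled and CKO-labelled mice (SD, n = 3 each). Across spots within a section, fibroblast and acinar enzyme shares were inversely related, with a mean Spearman rho of -0.73 ± 0.11 in the WT-labelled and -0.49 ± 0.12 in the CKO-labelled mice (exact permutation p = 0.1, adjusted p = 0.4 over 4 lists). Both are shares of the same UMIs of a spot, of which acinar enzymes take a large part, so the measure itself favours a negative rho. The nearest values of the groups were -0.607 and -0.608, and at an equal depth of 1000 UMIs per spot the groups overlapped (difference 0.18, exact permutation p = 0.2). For macrophage genes rho was -0.59 ± 0.08 and -0.61 ± 0.02 (exact permutation p = 0.7), for neutrophil genes -0.21 ± 0.10 and -0.36 ± 0.06 (exact permutation p = 0.2), and for Reg and injury genes 0.44 ± 0.11 and 0.60 ± 0.16 (exact permutation p = 0.3).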

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

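The tests in this part were chosen only after the results were seen, except for the interaction test, the fit without the WT-labelled 24 h replicate 1 and the fit to spots with a high acinar enzyme share, although the use of those 2 fits for the patterns here was also decided afterwards. The planned interaction test, with 1 mouse per label at 48 h, called 36 genes. Fitted log2 interactions were 11.78 for Ighg2b, 10.06 for Glycam1, 9.46 for Dusp2, 6.96 for Cd209b, 6.68 for Ighg3 and 6.06 for Ccl5, and -4.01 for Gkn3, -3.68 for Hbb-bt and -3.11 for Hba-a2. Ighg2b and Dusp2 were at 0 in the WT-labelled 48 h section, so their fitted values depend on the prior count and give no bound.

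Hbp1 was not lower in the CKO-labelled sections. If Hbp1 of spots outside the acinar regions hid its loss, the acinar regions would show less of it in the CKO-labelled mice, but there the ratio to the WT-labelled mice was 1.94, with no overlap of the groups, and in the spots of each mouse above its median share of acinar enzymes, which do not rest on the regions, the log2 change of Hbp1 was 0.62 with TMM. An exchange of genotype labels between the groups cannot be told apart from correct labels by Hbp1, and Ptf1a, the gene p48Cre is named for, does not settle it. A Cre inserted into Ptf1a would lower that gene, and its log2 change of -1.04 (SE 0.33, adjusted p = 0.253, from 2.8e-04 to 1.0 over the alternatives) lies in the direction of the labels, but it missed the threshold and the line is not stated. Probes outside the deleted exons, a compensating rise of the remaining transcript and incomplete deletion stay open and were not tested.

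Islet genes were higher in the CKO-labelled sections, with a median log2 change of 2.25 (SD 0.27) over 6 genes. These were taken because they passed, against a median of 1.41 over the whole list, and each SD here is over genes. Without the spots led by islet hormones the median was 1.77 (SD 0.40) and 5 of the 6 passed. Removal of all spots within 2 steps of one left a median of 1.77 (SD 0.53) and 3 of the 6 calls. The difference was thus not confined to the removed spots. With genes chosen for passing, neither removal can exclude islet RNA in the spots that were kept. Without the WT-labelled 24 h replicate 1, which had no islet-led spot, the median was 1.64 (SD 0.18) and none of the 6 passed in edgeR. With 1 WT-labelled mouse left at 24 h, sampling of islets by single sections cannot be told apart from an effect of genotype, which stays open.

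The lymphocyte and plasma cell genes Cd3e, Cd3d, Trac, Trbc2, Cd79b and Igha were higher in the CKO-labelled sections, with a median log2 change of 2.07 (SD 0.41) over these 6, taken because they passed, against medians of 1.26, 1.09 and 1.03 over the whole T and NK cell, B cell and plasma cell lists. Without the lymphoid region, 97 of whose 98 spots lie in the CKO-labelled 48 h section, the median was 0.77 (SD 0.28) and none of the 6 passed in edgeR, so a lymph node or lymphoid aggregate caught in that section is a candidate source of the calls. A difference already present at 24 h cannot be told apart from none, because in the 24 h mice alone the median was 0.66 (SD 0.22), above 0 for all 6 genes, and none passed.

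The 6 mice allow 10 splits of 3 against 3, too few for a share under 0.05. The split by genotype label gave 55 genes in whole sections, where the highest of the others gave 88 and 2 splits gave as many as the real one, itself included. In the acinar regions it gave 18 genes, the highest other 47, with 3 such splits. For gene lists it gave 19, the highest other 20, with 2 such splits.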

How the results depend on the processing

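Alternatives described as added were chosen after the data were seen. These are other dispersion settings, the 24 h mice alone, removal of spots of single regions, TMM scaling of the Hbp1 level, no TMM in the regions, every alternative in the Arg1-led region, and leaving out mice for shares. No named gene past the threshold changed direction under any alternative run for it, while most lost their call under some, and most had been named for groups without overlap. Of all 55 genotype calls, 1 changed sign without the WT-labelled 24 h replicate 1, 4 without the WT-labelled 48 h mouse and 3 without the CKO-labelled 48 h mouse. Both fits without a 48 h mouse used the 24 h mice alone for genotype. Of the alternatives for genotype in whole sections, which called 55 genes, DESeq2 called 1, no TMM 32, no covariate 0 in edgeR (with 481 genes at an unadjusted p under 0.05), the file-name block 36, limma-voom 645 (328 higher and 317 lower) and the mean over spots 4 (Ctrc, Ins2, Ctrb1 and Gm4737). Added settings called 35 (robust dispersion), 19 (the edgeR 4 method), 13 (24 h mice), 27 (no lymphoid or islet spots) and 34 (no lymphoid spots). At 24 h, with 14 genes, DESeq2 called 0 and no TMM 7. For the interaction, with 36, they called 11 and 12, the added edgeR 4 method 17 and removal of lymphoid and islet spots 1. For time, with 304, they called 107 and 133. In the acinar regions, with 18, no centring called 5, a random 100 spots 9, no TMM 8 and the 24 h mice 6. In the Arg1-led region, with 9, robust dispersion called 19. Leaving out each mouse in turn gave 3 to 110 genes for genotype, 2 to 100 at 24 h, 8 to 209 for the interaction, 38 to 375 for time, 10 to 52 in the acinar regions and 2 to 30 in the Arg1-led region. Gene lists, 19 for genotype and 10 for time, fell to 0 with an estimated correlation and to 0 with fry in a single direction for both, while fry without regard to direction called 1 time list, mesothelium (adjusted p = 0.0126). For genotype they numbered 12 in the 24 h mice, 12 without lymphoid spots, 11 in the acinar regions of the 24 h mice and 11 there without TMM, and 10 to 19 over single mice left out, against 10 to 18 for time. The median of reported HBP1 targets, -0.05, went to 0.30 without TMM, to 0.0327 without the spots of region 4, and from -0.21 to 0.05 over single mice left out. The log2 change of Hbp1, 0.19, went from -0.046 to 0.47 in the same way, and its ratio of 1.49 was 1.14 with TMM scaling. With acinar and Reg genes out of the denominator 2 marker shares separated the labels in place of 0, and resolution 1 gave 12 regions in place of 7. The cause of these moves was not tested. The difference in islet region share, 3.18 points, ranged from 1.96 to 4.11 over single mice left out, and that in lymphoid region share, 4.42 points, from 0.04 without the CKO-labelled 48 h mouse to 6.63 (both added). The interaction could not be fitted without either 48 h mouse. The CKO-labelled 48 h mouse could not be left out in the Arg1-led region, where it was not used. Depth limits the WT-labelled 48 h section most, with 2969981 UMIs.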

Other observations

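The test in this part was chosen after the values of Ctrc were seen and before its own result was. Ctrc, which encodes chymotrypsin C, a protease that degrades trypsin in the pancreas, had 258 and 300 UMIs in the WT-labelled 24 h replicate 2 and the WT-labelled 48 h section. It had 12242 UMIs in the WT-labelled 24 h replicate 1 and 62524, 60082 and 12824 UMIs in the CKO-labelled sections. That is 49.6 and 127 CPM against at least 2113 CPM in the other 4 mice. The labels give a C57BL/6J background for all mice, and the reference annotation of that strain lists Ctrc as a transcribed pseudogene. A candidate explanation is that mice with high Ctrc carry a chromosome segment of another strain there. If so, genes near Ctrc may split the mice alike. Of 270 tested genes within 10 Mb, 2.22% had an unadjusted p under 0.05 for that split, against a median of 1.11% and a 95th percentile of 3.70% over 56 windows of as many genes elsewhere. The value lies between them, so the explanation stays open. If it holds, the genotype labels differ in part in a gene that itself acts in cerulein pancreatitis.

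Gm4737 had 897 and 324 UMIs in the CKO-labelled 24 h replicate 1 and the CKO-labelled 48 h section and 4 to 18 UMIs in the 4 other sections.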
